A study of Mus musculus with 12 samples.

How the data were processed

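The series holds liver RNA of 8-week-old male C57BL/6 mice that were wild type or carried a liver-specific knockout (cKO) of Mettl3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) into mRNA. Per the labels' protocols, fragmented RNA was incubated with an anti-m6A antibody for 2 hours at 4 °C and with protein-A beads for another 2 hours, bound RNA was eluted with free N6-methyladenosine, and both the immunoprecipitate (IP) and the input RNA without precipitation were sequenced as 150 bp paired-end reads. The labels give 12 samples in 4 groups of 3 libraries (wild-type IP, wild-type input, cKO IP and cKO input).

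Values that can be tied to a genotype were used for 1 input library and 1 IP peak list of each genotype. Their columns and lists are named case and control, each followed by a 1. Control was read as wild type and case as cKO because the series has just these 2 genotypes. The labels do not state this reading. They number the livers of each genotype 1 to 3, and the 1 in the names may be that number, but no label states it. The libraries are therefore called the library labelled control and the library labelled case. A further 8 columns of an expression table and 4 peak lists are named by library numbers that match no label, and they were not used in any step.

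The authors deposited FPKM values (fragments scaled by transcript length and library size) for 22564 genes. This scaling did not bring the 2 libraries to equal totals. With mitochondrial genes included, FPKM summed to 190480 in the control input and 339949 in the case input. In these sums 8 mitochondrial genes were at 0 in the control input and none in the case input, among them mt-Co1, at 69917 FPKM in the case input. Mitochondrial genes were set aside below, and differences of FPKM as deposited carry any inequality left among the other genes. The setting with equal non-mitochondrial totals scales FPKM by the totals of the deposited counts of these other genes, not by the FPKM sums. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cuffdiff, Cufflinks and the mouse build mm10, without roles or order. The authors deposited beside them a signal headed as counts, which is not a raw count: its low values are whole multiples of a step that differs between the libraries. Dividing by that step gave fragments. Of the values above 0, 92.6% in the control input and 91.6% in the case input then came out whole within 0.02 fragments. The depth recovered this way was 1737350 fragments for the control input and 3564792 for the case input, of which 23.9% and 27.6% lay in mitochondrial genes. Since the remaining values were not whole and there was 1 library per genotype, no count test was run.

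Per the file headers, the deposited peak lists give each peak a fold enrichment (a ratio of IP over background), a score (the p-value on a negative log10 scale, times a constant) and a false discovery rate in percent, as the authors' peak caller wrote them. Peak names begin with MACS; its version, its settings and the input used as background are not given in the sources used here. One list was deposited per library. These values are the authors' own and were used to describe, rank or filter peaks within a list, not to compare a peak between lists. Starts in the peak lists and gene loci count from 0: after 1 was added, 307 peak starts of the control list and 250 of the case list met a gene start of the assembly GRCm38.p6 (the same coordinates as mm10), against 22 and 24 without it. Coordinates are given counting from 1. A locus can span neighbouring genes that the authors' tool bundled.

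For expression, genes on the mitochondrial chromosome (13) were set aside, because 8 of them were listed at 0 in the control input and none in the case input, and genes with a mean FPKM of at least 1 over both libraries were kept (9584 genes). The measure was the difference of log2(FPKM + 1), case minus control, which understates the difference of low genes. A gene counted as higher or lower in the case input when this reached 1, a 2-fold difference. The design fixed before the data were examined (limma on log2(FPKM + 1), and camera and fry for gene lists) needs at least 2 libraries per genotype and could not be run, so no p-value, standard deviation or standard error is given. For genes, 95% exact intervals of fragment counts (Poisson) and of their ratio (Clopper-Pearson) are given. They cover counting error only, and PCR copies are not independent molecules. For gene lists, the list's median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Genes carrying peaks were placed among 1000 such lists. The 37 lists (745 entries) covered liver metabolism, sex-biased, zonal, clock, stress and interferon genes, markers of other cell types, and the m6A machinery. Of the entries, 733 were found in the table, 8 of them under an older symbol, and 31 lists had at least 5 measured members. Intervals of list medians are binomial, and intervals of shares are Wilson intervals unless stated.

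Peaks shared at least 1 base to count as overlapping. Genes were compared by whether a list names them.

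Genes were named by a rule fixed before the data were examined: Mettl3 and the other m6A writers, readers and erasers, the 12 largest differences in each direction, up to 4 members of each list, the 5 genes of highest mean fold enrichment with a peak in 1 genotype's list, the 5 highest with a peak in both, and genes of a list of known m6A-marked transcripts that have a peak. The rule's conditions on p-values and replicates could not apply. In their place, the 12 largest were taken among genes with at least 3 fragments in both inputs, and list members by the size of their difference. A gene listed at 0 in an input is said to be so and given no fold, since such a 0 can be a failed estimate.

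The alternatives planned were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, quantile normalization, median centring, a fold enrichment of at least 4, the 5000 highest peaks and a reciprocal overlap of 50%. Added after the data were seen were keeping mitochondrial genes, scaling to equal non-mitochondrial totals, at least 3 fragments in both inputs, and a false discovery rate of at most 15%. The procedures were tested on simulated data. Fragments were drawn at the real depths for 9584 genes of the input comparison, and both libraries were then put on 1 depth. The 2-fold rule took 86.6% of genes changed 4-fold, 100% of those changed 8-fold, 28.4% of those changed 2-fold and 0.554% of unchanged genes. The draws held counting error only and no shift between libraries. The deposited FPKM had a median log2 ratio of 0.41, so these rates do not hold for the rule as run on them. For the gene lists, 20 of 20 simulated lists of 10 genes raised 2-fold passed the 97.5th percentile, and 4% of 200 unchanged lists fell outside the 2.5th to 97.5th percentiles. The raised lists were drawn repeatedly from the same raised genes, and the unchanged lists were random draws of genes simulated independently. Members of the real lists can vary together, so these rates are not error rates of the real lists' percentiles. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.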

Results

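Input RNA and m6A peaks of mouse liver were compared between the library labelled control, read as wild type, and the library labelled case, read as liver-specific Mettl3 cKO. Each genotype had 1 input library and 1 peak list, so the differences below have no replicate check and compare these libraries, not the genotypes. The control input held 1737350 fragments and listed 14132 genes above 0, and the case input held 3564792 fragments and listed 12908 genes above 0. Intervals are 95% intervals of counting error.

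The targeted gene was examined first, as a check of the labels. Mettl3 (chromosome 14, 52258811 to 52305128, minus strand, mm10) was listed at 3.44 FPKM in the control input, from 12 fragments (interval 6.20 to 21.0), and at 2.91 FPKM in the case input, from 17 fragments (interval 9.90 to 27.2). The ratio of scaled fragments, case over control, was 1.21 with an interval of 0.545 to 2.78, so that no difference was detectable at this depth. The labels do not say which part of the gene was deleted, and a gene-level value does not show it. The input values therefore do not set the library labelled case apart as a knockout, and each direction below is drawn from the labels alone. Of the other m6A writers, Wtap had 5.44 FPKM in the control and 4.51 in the case input, and Mettl14 had 0.452 and 0.493. None of the 9 writers with a mean of at least 1 FPKM differed 2-fold, and with equal totals 1 was lower. Among 10 measured readers and erasers, 9 lay within 2-fold on the log2(FPKM + 1) scale, which understates low genes, and with a pseudocount of 0.1 2 were higher and 1 lower. By FPKM alone the demethylase Fto (4.29 in the control and 9.25 in the case input) and the reader Ythdf3 (2.73 and 6.23) were 2.16 and 2.28 times as high in the case input. The demethylase Alkbh5 had 6.25 and 10.2 FPKM. Fmr1 was lower by FPKM, at 6.00 in the control and 2.46 in the case input, but its fragments numbered 51 and 61.

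The first comparison asked how liver gene expression differed between the genotypes. The case input was higher in genes of hepatocyte metabolism and lower in genes of the other liver cell types. Of 253 measured genes in 12 lists of hepatocyte metabolism, secretion and transcription factors, 181 were at least 2-fold higher in the case input and 8 lower. With quantile normalization 101 of them were higher and 9 lower, and with equal non-mitochondrial totals 107 and 12. Of 63 measured markers in 9 lists of other cell types, 56 were at least 2-fold lower and 1 higher. Without the filter on mean FPKM, 62 of 122 were lower, 2 higher and 58 within 2-fold. The median log2 ratio was then -1.04, against -2.50 with the filter. The markers added had a mean under 1 FPKM, where the measure understates differences. The lists were pooled after the data were seen. Whether lists of lipid, interferon, stress and iron genes differed apart from the lower markers of other cell types was not tested. Over all 9584 genes, 2260 were at least 2-fold higher in the case input and 1264 lower, and the median log2 ratio was 0.41, so medians of lists outside the 2.5th to 97.5th percentiles of matched lists are also given relative to this shift. This split depended on scaling: with equal non-mitochondrial totals, 759 genes were higher and 1989 lower, with quantile normalization 1373 and 1487, and with median centring 1518 and 1529.

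Lipid synthesis genes stood among the largest differences. Of 19 measured lipogenesis genes, 17 were at least 2-fold higher in the case input, and their median log2 ratio of 2.29 (1.88 above the median of all genes) passed each of the 10000 matched random medians. Lpin1, a phosphatidate phosphatase of triglyceride synthesis, had 4.16 FPKM in the control and 74.3 in the case input (127 against 2649 fragments). Thrsp, a lipogenic regulator, had 12.6 and 176 FPKM, Fasn, the fatty acid synthase, 4.20 and 54.6, and the elongase Elovl6 0.895 and 11.1. Of 21 cholesterol synthesis genes, 18 were higher, with a median log2 ratio of 1.82 (1.41 relative to all genes) at the 100th percentile. Insig1, an ER regulator of sterol synthesis, had 18.7 FPKM in the control and 100.05 in the case input, and Idi1 had 3.26 and 20.4. The 17 measured genes of lipid droplets and lipid uptake divided, with 6 higher and 5 lower. Cideb, a lipid droplet protein, had 17.0 and 69.3 FPKM, whereas Lpl, the lipoprotein lipase, had 11.5 and 0.434 and Fabp4 had 20.6 and 1.54.

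Bile acid genes were higher in the case input in 22 of 23 measured members, with a median log2 ratio of 1.81 (1.41 relative to all genes); 14 were higher with quantile normalization and with equal totals. The bile salt export pump Abcb11 had 7.66 FPKM in the control and 44.3 in the case input, the sterol hydroxylases Cyp27a1 and Cyp7b1 17.4 and 1.51 against 100.2 and 29.5, and the uptake transporter Slco1a1 1.07 against 29.6. For the urea cycle and amino acid breakdown, 18 of 20 were higher, with a median of 2.12 (1.71 relative to all genes). Cps1, which makes carbamoyl phosphate for the urea cycle (chromosome 1, 67123026 to 67231261), had 63.5 FPKM in the control and 533 in the case input, and the serine dehydratase Sds had 17.3 and 134. In glucose and glycogen metabolism 14 of 17 were higher, with a median of 1.97 (1.56 relative to all genes). With quantile normalization and with equal totals the medians were 1.30 and 1.39 for the urea cycle list, 1.17 and 1.27 for glucose (12 and 10 higher), 1.31 and 1.12 for cholesterol (13 and 12 higher), 1.43 and 1.63 for lipogenesis (13 and 14 higher) and 1.21 and 1.085 for bile acids. The glucose-6-phosphatase G6pc had 27.4 and 137 FPKM. Pklr, the liver pyruvate kinase, had 2.31 and 35.3 FPKM but 3 and 547 fragments, so its FPKM and fragment ratios differ. Such a disagreement of over 2-fold was found for 352 of 9109 genes.

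Phase I drug metabolism (21 of 24 higher, median 1.55, or 1.14 relative to all genes) and liver transcription factors (18 of 21 higher, median 1.48, or 1.07) also lay above the 97.5th percentile of matched lists. The nuclear receptor Ppara had 7.41 FPKM in the control and 40.9 in the case input, and Onecut1 had 3.05 and 19.4. With quantile normalization 11 phase I genes and 11 transcription factors were higher, and with equal totals 11 and 10. Fatty acid oxidation was higher in 14 of 21 genes, yet its median of 1.30 was at the 94.7th percentile. For phase II conjugation, 12 of 24 were higher and the median was at the 78.4th percentile. Secreted plasma proteins were higher in 16 of 29 genes, and their median of 1.03, which became 0 under quantile normalization, was at the 31.6th percentile of equally abundant genes. In the acute phase list 8 of 20 were higher and 1 lower, at the 26.2nd percentile. Oxidative phosphorylation genes of the nucleus were higher in 23 of 26, at the 98.0th percentile, a position outside the 2.5th to 97.5th percentiles in 6 of 9 settings. With quantile normalization and with equal totals, 2 of the 26 were higher. On these 2 scales the genes higher numbered 3 and 4 for fatty acid oxidation, 6 and 6 for phase II, 0 and 5 for secreted proteins and 3 and 4 for the acute phase.

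The largest single differences towards the case input were in Selenbp2 (9.64 against 303 FPKM, 77 against 2716 fragments), Mup7 (44.1 against 874 FPKM) and Serpina1e (67.3 against 1081 FPKM), followed by Slco1a1, Lpin1, Mup11, Thrsp, 2810007J24Rik, Cyp7b1, Ttc39c, Pex16 and Pklr. The Mup, Serpina1, Selenbp and Cyp2d genes have near-identical copies among which fragments could be split, and their values are uncertain. In the control input Mup12, Mup18, Mup16 and Mup1 were listed at 0, beside 540, 102.9, 41.7 and 30.7 FPKM in the case input.

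**Figure D1:**
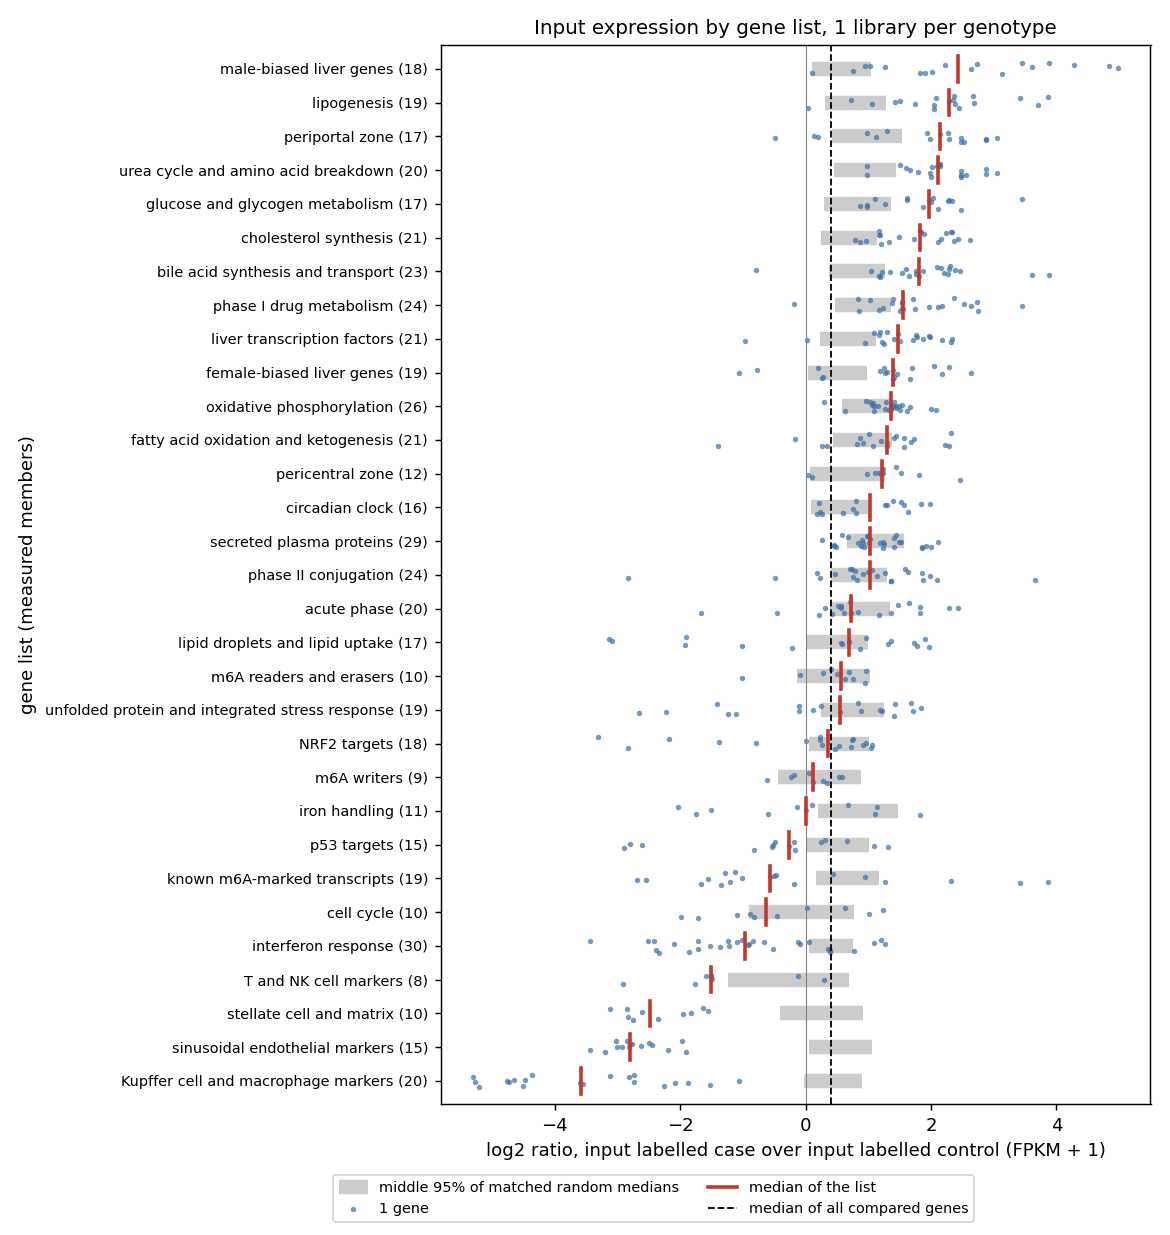
Log2 ratio of input FPKM + 1, case over control (horizontal axis), for measured members of the 31 gene lists with at least 5 (vertical axis), with 1 library per genotype. Points are genes, red bars list medians, grey bars the 2.5th to 97.5th percentile of medians of random lists matched on mean expression, and the dashed line the median of all genes, 0.41; list medians run from -3.58 for macrophage markers to 2.43 for male-biased genes.

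Markers of non-parenchymal cells were lower in the case input. Of the Kupffer cell and macrophage list 20 of 20 measured genes were at least 2-fold lower, with a median log2 ratio of -3.58 (-3.99 relative to all genes), below each of the matched random medians. C1qc, C1qb and C1qa, the subunits of complement C1q, had 68.7, 83.9 and 67.0 FPKM in the control and 0.766, 1.29 and 1.70 in the case input. The Kupffer cell lectin Clec4f had 89.9 and 2.36 FPKM. Csf1r, the macrophage growth factor receptor, had 37.5 FPKM from 785 fragments in the control input and 0.00123 FPKM from 0 fragments in the case input, and is not ranked among the largest differences for that reason. All 15 measured sinusoidal endothelial markers were lower, with a median of -2.81 (-3.22 relative to all genes). The scavenger receptor Stab2 had 41.9 and 2.96 FPKM but 635 and 121 fragments, so its ratio was 0.0706 by FPKM and 0.163 by scaled fragments, and the endothelial adhesion protein Pecam1 had 19.9 and 1.58. Of 24 stellate cell and matrix genes 10 passed the filter on mean FPKM. All 10 were lower, with a median of -2.48 (-2.89 relative to all genes), among them the collagen gene Col3a1 (7.44 against 0.254 FPKM) and Dcn (37.1 against 4.30 FPKM). Over the 9 settings, 1 of them without the filter, this median ran from -3.16 to -1.16. For T and NK cells 8 of the 19 genes in the table passed the filter. Of these 6 were lower, with a median of -1.51 at the 0.540th percentile. Over the 7 settings with a median, it ran from -3.04 to -0.85. The 12 largest differences in this direction were C1qc, C1qb, Clec4f, C1qa, Lyz2, Ctss, Cd5l, H2-Eb1, Cd74, Cxcl2, Rgs1 and Sdc3, with Cd74, the class II invariant chain, at 194 and 9.79 FPKM.

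Interferon response genes were lower in 15 of 30 members and higher in 3, with a median of -0.97 (-1.37 relative to all genes) below each of the random medians. With equal totals 20 were lower and 0 higher, with a median of -1.54, and with quantile normalization and median centring 18 and 1. At a mean FPKM of at least 5, 4 of 15 were lower, with a median of -0.087 at the 1.38th percentile. Rsad2 had 8.56 FPKM in the control and 0.674 in the case input, and Ifit2 had 9.70 and 1.04. p53 targets lay at the 0.270th percentile, although 10 of 15 were within 2-fold, with 2 higher and 3 lower, or 0 and 6 with equal totals: Cdkn1a, the cell cycle inhibitor p21, had 117 fragments in the control and 11 in the case input, and Plk2 had 33.7 and 3.97 FPKM. Stress genes divided. Ppp1r15a and Atf3, of the integrated stress response, had 49.6 and 37.8 FPKM in the control and 7.04 and 7.31 in the case input, while the ER protein gene Herpud1 had 62.0 and 224. In that list 7 of 19 were higher and 5 lower, against 2 and 6 with quantile normalization, 5 and 5 with median centring and 3 and 5 with equal totals. Its median of 0.55 fell below 0 under quantile normalization and under equal totals. Heme oxygenase Hmox1 (32.1 against 2.34 FPKM) was lower among 18 NRF2 targets, whose median was 0.36 and mean -0.14. That median too was below 0 under quantile normalization and equal totals. Cell cycle genes showed 3 of 10 lower and 2 higher, at the 6.39th percentile, and 5 lower and 0 higher with median centring and with equal totals.

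The second comparison asked where m6A peaks were called in each genotype. The control list held 17175 peaks in 7450 genes, covering 5.04 megabases with a median length of 209 bases. The case list held 17277 peaks in 8150 genes, covering 4.93 megabases with a median length of 200 bases. The authors' median fold enrichment was 28.5 within the control list and 14.95 within the case list, and their median false discovery rates were 1.66% and 12.3%. A rate of up to 5% was given to 96.9% of control peaks and 0.0232% of case peaks. At a rate of at most 15% the lists held 17175 and 12913 peaks. In both lists 30.4% of the peaks that could be placed within a gene lay in its last 10% towards the 3′ end. Their median distance to that end was 7217.5 bases in the control and 8147.5 in the case list, with 24.8% and 23.6% within 2000 bases. Positions were taken over the whole gene with introns and no expected share was computed, so an excess near the 3′ end was not tested. Of control peaks, 35.5% (34.8 to 36.2%) were overlapped by a case peak by at least 1 base, and of case peaks 35.3% (34.6 to 36.1%) by a control peak, with 1614 peaks at identical coordinates. Genes with a peak in both lists numbered 5411, those in the control list only 2039 and those in the case list only 2739. The case list also had more genes of its own at a fold enrichment of at least 4 (2202 against 2694) and among the 5000 highest peaks (1790 against 1859). At a false discovery rate of at most 15% the order turned (2809 against 2408), but that threshold removed 0 control peaks and took the case list's peaks of highest fold, whose maximum went from 3441 to 126.

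Among genes with a peak in 1 list, the highest mean fold enrichments of the control list were at Ppp1r3g (chromosome 13, 35968444 to 35970115), A630007B06Rik, D130043K22Rik, Prune and Bet1l. In the case list they were at Aim2, a cytosolic DNA sensor (chromosome 1, 173464971 to 173465341), Zfp791, Sdpr, Slc44a2 and Gpr65. Among genes in both lists they were at Rbmx, Rpl17, Tnpo2, Gm21738 and Ncl. Several of these genes were near the floor of the input, where a ratio over background is uncertain. Zfp791, Slc44a2 and Gpr65 had 0.106, 2.9e-05 and 0.0802 FPKM in the case input, and Aim2 and Sdpr 0.820 and 1.05. D130043K22Rik had 0.153 FPKM in the control input, and Gm21738 was listed at 0 in both. The highest peaks of Aim2, Zfp791, Sdpr, Slc44a2 and Gpr65 had a false discovery rate of 17.94%. Of the 21 known m6A-marked transcripts found in the table, 11 had a control-list peak and 14 a case-list peak. Of all 9584 compared genes, 6290 had a control-list peak and 6267 a case-list peak, so these counts show no clear excess. Jun, Myc, Hsp90aa1, Cebpb, Creb1, Sox9, Sirt1 and Ppara had peaks in both. Lpin1 had 15 control peaks and 0 case peaks, and Fasn 11 and 0, with Eef2 also in the control list alone. Socs3, Klf4, Junb, Fos, Pparg and Cry1 were in the case list alone. No peak of either list was assigned to Mettl3.

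Of the 31 lists with a median, 25 held more peaks under the label whose input gave the lower median level, 5 held more under the other label and 1 held equal numbers. The 5 were m6A writers, m6A readers and erasers, NRF2 targets, iron handling and known m6A-marked transcripts, of which the last had a median log2 ratio of -0.57 with 49 control and 21 case peaks. With quantile normalization the numbers were 24, 5 and 2, and with equal totals 27, 3 and 1. The lists share members, such as 11 of 17 periportal and 10 of 20 urea cycle entries that are also in another list. They are therefore not independent counts, and the iron handling median was -0.00031. Among the 25, lipogenesis genes held 98 control peaks and 22 case peaks, and urea cycle and amino acid genes 112 and 13, of which Cps1 had 28 and 1. Kupffer cell and macrophage genes held 2 control peaks and 37 case peaks: 2 genes of the list had a control peak and 16 a case peak. Sinusoidal endothelial genes held 11 and 55, with Stab2 at 3 and 13, and stellate and matrix genes 5 and 44. These 5 lists kept that order of peaks at a fold enrichment of at least 4, among the 5000 highest peaks and at a false discovery rate of at most 15%, where 26, 26 and 28 of the 31 lists ran opposite to the inputs.

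The third comparison asked how genes with peaks were expressed. Genes with a control-list peak only (1576 compared) had a median log2 input ratio of 0.88 (0.81 to 0.93), above each of the 1000 random medians matched on expression. Those with a case-list peak only (1553) had a median of -0.31 (-0.43 to -0.20), below each of them. The match was on the mean of both inputs, not on the input of the same label. These percentiles therefore cannot show whether peaks were called more readily where that input was low. Genes in both lists (4714) had a median of 0.45, at the 41.8th percentile. At a mean FPKM of at least 5 their median of 0.68 was at the 0.250th percentile, and with equal totals it was -0.12. The 6290 genes of the control list as a whole had a median of 0.55, which was -0.035 with equal totals, where its percentile was still 100. Across bins of the input ratio, genes with a control-list peak went from 17.9% (11.1 to 27.4%) of the 84 genes below a log2 ratio of -3 to 85.8% (81.4 to 89.3%) of the 303 genes between 2 and 3, and were 77.4% (60.2 to 88.6%) of the 31 genes at 3 or above. Genes with a case-list peak were 72.6% (62.3 to 81.0%) in the lowest bin, 81.2% (76.8 to 84.9%) between -3 and -2, 44.9% (39.4 to 50.5%) between 2 and 3 and 22.6% (11.4 to 39.8%) at 3 or above. Genes are not independent replicates, and these shares describe the libraries.

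**Figure D2:**
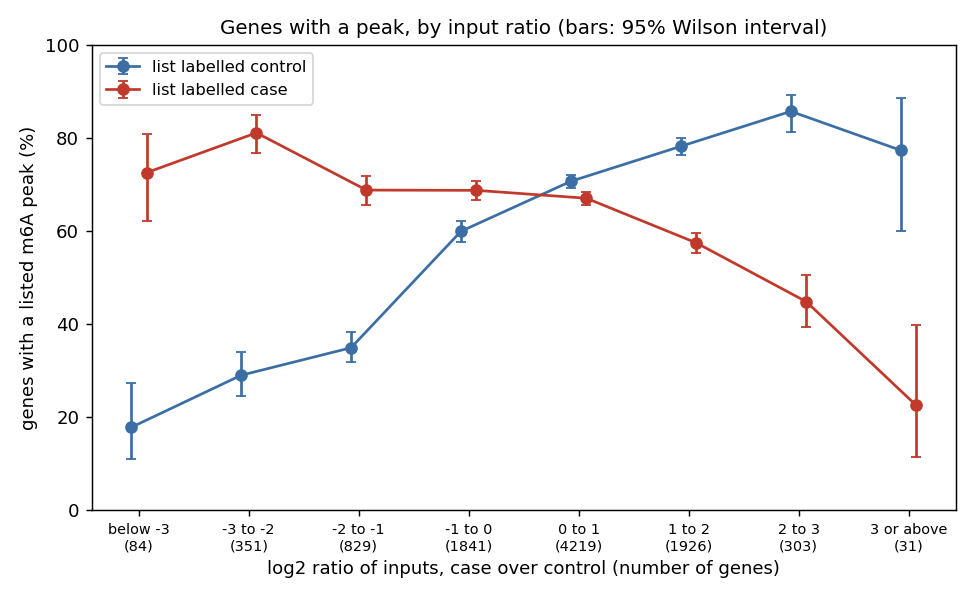
Percentage of compared genes with at least 1 m6A peak in the list labelled control (blue) or case (red), by the log2 ratio of the inputs, case over control; numbers of genes stand under each bin and bars are 95% Wilson intervals. The blue line climbs from 17.9% in the lowest bin to 85.8% between 2 and 3 and is at 77.4% in the highest bin, and the red line is at 72.6%, 81.2%, 44.9% and 22.6% in the lowest, the second, the last but 1 and the highest bin.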

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

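The settings on mitochondrial genes, equal totals, at least 3 fragments and a false discovery rate of 15% were chosen after the data were seen; the others were planned. Genes at least 2-fold higher in the case input numbered 2260, against 1373 with quantile normalization and 759 with equal totals; genes lower numbered 1264, against 369 at a mean FPKM of at least 5 (fewer genes tested) and 1989 with equal totals. Lists above the 97.5th percentile numbered 10 to 12 and below the 2.5th 7 to 10 over the 9 settings. Genes of hepatocyte lists higher in the case input numbered 181, against 101 with quantile normalization and 107 with equal totals. For other cell types 1 was higher and 56 lower of 63. At a mean FPKM of at least 5 they numbered 0 and 36 of 36, and without a filter 2 and 62 of 122. The iron handling median of -0.00031 became 0.051 at a mean FPKM of at least 5, -1.07 with quantile normalization and -0.73 with equal totals. Lists with more peaks under the label of the higher input numbered 5, against 3 at a false discovery rate of at most 15%, 3 at a mean FPKM of at least 5 and 3 with equal totals, all counted after the data were seen. Taking the 5000 highest peaks leaves 5000 in each list by construction and 1522 genes in both. Overlap of control and case peaks was 27.7% and 27.9% with the 5000 highest, 27.3% and 27.1% with reciprocal overlap, 23.5% and 31.2% at a false discovery rate of at most 15%, and 34.1% for control peaks at a fold enrichment of at least 4. Median log2 ratios of genes in the control list, in both, in the control list only and in the case list only were, with quantile normalization, 0.27, 0.18, 0.50 and -0.45; with median centring 0.31, 0.21, 0.64 and -0.55; with equal totals -0.035, -0.12, 0.27 and -0.83; and at a mean FPKM of at least 5, 0.81, 0.68, 1.20 and -0.20. For the first 3 of these groups they were 0.68, 0.56 and 1.05 with a pseudocount of 0.1 and 0.45, 0.39 and 0.68 without a filter. With the 5000 highest peaks the first 2 had 0.67 and 0.49, and with at least 3 fragments the last had -0.14. Beyond the alternative's own construction, the cause was not tested. No paired analysis was possible because each genotype had 1 library. For the same reason the replicate block, the table block, leaving out each replicate and eBayes without trend were not run. Depth limits genes such as Mettl3, with 12 and 17 fragments.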

Other observations

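Further gene groups, all fixed before the data were examined, stood as follows in the inputs. Male-biased liver genes were at least 2-fold higher in the case input in 15 of 18 and female-biased genes in 14 of 19, with medians of 2.43 and 1.39 (2.02 and 0.98 relative to all genes), both above the 97.5th percentile of matched lists. Y-linked genes were higher in the case input too, as given below, and a link to either list was not tested. Female-biased genes higher numbered 8 of 19 with quantile normalization, and 4 of 19 with equal totals, where 2 were lower. Sult3a1, a female-biased sulfotransferase, was listed at 0 in the control and 5.23 FPKM in the case input. By liver zone, periportal genes were higher in 13 of 17, with a median of 2.15 (1.74 relative to all genes) at the 100th percentile. That median was 1.22 at its lowest over the 9 settings, and 11 of the 17 genes are also in another list. Pericentral genes were higher in 9 of 12, with a median of 1.22 at the 96.5th percentile. They were higher in 5 with quantile normalization, 4 with median centring and 3 with equal totals. The lists' difference was not tested. Cyp2f2, a periportal cytochrome, had 71.7 and 419 FPKM. Of 16 clock genes 8 were higher, and 3 with equal totals, at the 97.4th percentile, with Per2 at 3.11 and 13.8 FPKM. Iron handling lay at the 0.535th percentile with 3 genes higher and 3 lower: the iron exporter Slc40a1 had 35.9 FPKM in the control and 9.97 in the case input, and the hormone gene Hamp had 94.2 and 335. With quantile normalization 0 were higher and 6 lower, and with equal totals 1 and 4. Known m6A-marked transcripts had a median of -0.57 (-0.98 relative to all genes), below each random median, with an interval of -1.34 to 0.95. Over the 9 settings that median went as low as -1.46. Of 19 measured, 4 were higher and 9 lower, with Lpin1 and Fasn higher and Klf4 (15.1 against 1.49 FPKM) and Socs1 (7.31 against 0.425 FPKM) lower. Lists with under 5 measured members were fetal liver genes (1 higher and 3 lower of 4), cholangiocyte markers (1 lower of 3), neutrophil markers (3 lower of 3), B cell markers (1 lower of 1), erythroid markers (1 higher of 2) and pancreas and fat markers (0 of 1 past 2-fold).

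All the tests that follow were chosen after the results were seen. The first pattern concerns genes with a peak in 1 list only. Those in the control list only were shifted towards the case input, with a median log2 ratio of 0.88. Those in the case list only were shifted towards the control input, with a median of -0.31. Genes in both lists had a median of 0.45, near the 0.41 of all compared genes. One candidate explanation is that the inputs, or the IP libraries, carry each other's labels: the area under the curve for ranking genes with a peak was 0.581 by the own and 0.703 by the other input for the control list, and 0.476 and 0.536 for the case list, a difference of at least 0.0598, but this ranking restates the pattern and decides nothing. A further reading is that labels were right and only hepatocytes of the knockout lost methylation. Of the 45 markers of macrophages, endothelium and stellate cells, 26.7% carried a control-list peak (12, against 27 to 38 among random genes with the same control input level). For all 63 markers of other cell types it was 16, against 37 to 51. The few control peaks of these lists had been seen before, and the match assumes that markers are methylated as often as other genes. This comparison therefore restates the pattern and does not decide the reading. Another candidate is peaks called over a low input of the same liver. In the control list 88.1% of 253 hepatocyte list genes carried a peak (223, against 167 to 193 among genes at the same control input). These genes were not in excess in the case list (127, against 120 to 148). The many control peaks of hepatocyte lists had also been seen before, so low-input peaks stay open for the control list. For the case list low-input peaks stay open as well. There 69.8% of all 63 markers of other cell types carried a peak (44, against 34 to 48 at the same case input), but 38 of the 45, against 23 to 36. Of 63 genes under 3 fragments in the case and at least 50 in the control input, 48 carried a case-list peak. At under 10 in the control input it was 803 of 11034, but 89.2% of these were under 3 in both inputs. These counts were made without the filter on mean FPKM. With a mean FPKM of at least 1, genes under 3 fragments in the case and at least 50 in the control input numbered 61. Of these, 46 carried a case-list and 14 a control-list peak. With the same filter and the inputs reversed (control under 3, case at least 50), 6 of 12 genes carried a control-list and 4 a case-list peak. Low-input peaks and an exchange of inputs or IP libraries cannot be told apart there, and IP and input from different livers were not tested.

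The second pattern is that no difference of Mettl3 was detectable between the inputs. Relative to the median gene its fragment ratio of 0.823 had an interval of 0.370 to 1.89, which holds both 0.5 and 1, so a halving hidden by counting error and no difference cannot be told apart with 12 and 17 fragments. A deletion of some exons and exchanged inputs were not tested, and both stay open.

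The third pattern is that Y-linked genes were lower in the control input, although the labels call all mice male. Ddx3y, Uty, Eif2s3y and Kdm5d, chosen after their values were seen, had 37 fragments together in the control and 256 in the case input, a ratio of scaled fragments of 5.91 with an interval of 4.17 to 8.58. Counting error is argued against by the lower bound of 4.17, above the median gene's ratio of 1.47. A different mix of cell types that moves X-linked copies alike is argued against by Ddx3x, Kdm6a, Eif2s3x and Kdm5c, whose ratio was 1.32 (1.21 to 1.44). RNA from another animal in the control input was not tested, and no biological explanation was tested.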
